A study of Mus musculus with 2 samples.

How the data were processed

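Single-nucleus RNA sequencing (10x Genomics) was measured in the liver of 1 Control and 1 Repair Drive mouse, from about 100 mg of frozen liver each, with 15000 to 18000 nuclei loaded, per the labels' protocols. The Control sample's description and its files carry different mouse numbers, so which mouse the Control library comes from is open. Each library came as 2 matrices of UMI counts per gene and barcode over 32289 features, which include the vector genes human FAH, tdTomato, Cas9 and eGFP. The uncorrected counts were made with Cell Ranger 6.1.2 per the file headers, with the mm10 reference and Seurat 4.0 named in the submitters' processing notes. The deposited ambient-corrected counts are named as the output of an ambient RNA removal tool, whose version and settings are not given in the sources used here. In these counts 10.2% of Control and 13.7% of Repair Drive UMIs had been removed. Both matrices held whole numbers and no depth scaling was found. Whether introns were counted is not given in the sources used here.

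The ambient-corrected counts were used for all main values. Of 8432 Control and 7731 Repair Drive barcodes, 8407 and 7454 had at least 500 UMIs, 8305 and 7365 of these at least 300 genes, and 8085 and 6952 of these at most 5% mitochondrial UMIs. Doublets, droplets with more than 1 nucleus, were scored with Scrublet (scanpy 1.11.5). Its automatic threshold marked 0.0371 and 0.0863% of nuclei, under the 0.5% set as a floor, so the nuclei with the highest scores were removed at a rate of 0.8% per 1000 nuclei. This removed 537 (6.64%) and 387 (5.57%) nuclei, and 7548 and 6565 were kept. The kept nuclei held 43304235 and 36052199 UMIs.

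Both libraries were clustered together without batch correction: counts scaled to a common total and log-transformed, 2000 variable genes without the vector genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 with seed 1. Each cluster was scored against fixed marker lists by the mean share of nuclei with each marker, relative to the cluster with the highest share. The highest score gave the name, with the suffix "-like", unless under 3 markers were found in at least 5% of nuclei. A cluster whose leading genes were markers of another class was set aside as mixed, and a shallow cluster without a class marker among its 10 leading genes was left unnamed. The small lymphocyte, mesothelial and cholangiocyte classes were used for shares only, since under 100 nuclei per library were too few for gene levels.

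Counts were summed per library over the nuclei of a class and divided by the class total to give CPM. Ratios are Repair Drive over Control, with exact 95% intervals from the 2 Poisson counts, and shares carry exact Clopper-Pearson 95% intervals. For a share of 0, the value it allows up to is 3 divided by the number of nuclei, below the upper end of that interval. A ratio against 0 counts is given as a lower bound with the 0 set to 3 counts, and such genes entered list medians at that bound. The median log2 ratio of 12734 well-counted genes in hepatocyte-like nuclei was 0.07 (quartiles -0.18 and 0.30). For shares of nuclei with a UMI, nuclei were thinned to 1000 UMIs by drawing without replacement, and shallower nuclei were left out. The zonation index was the pericentral share of UMIs among pericentral and periportal list genes. A cycling nucleus had UMIs of at least 2 G2/M genes.

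Named genes followed a rule fixed before the data were examined, as were the gene lists, markers, comparisons and most alternatives. Among 7121 genes with at least 100 counts and at least 20 CPM in 1 library, the 12 highest and 12 lowest ratios in hepatocyte-like nuclei were named if the uncorrected counts went the same way by over 1.5-fold, along with Fah, Apoa1, Apoc3, Apoa4, Apoa5, F9 and Alb and the leading members of each list, of which some are not reported here. In other classes genes were eligible with at least 50 counts and a CPM in 1 library above that in hepatocyte-like nuclei of both. These were 3929 endothelial-like, 2647 Kupffer/macrophage-like and 3623 stellate-like genes. The 3 highest and 3 lowest were taken, and a second condition on the uncorrected counts was added after the values were seen. List members with at least 20 counts were measured, and members were counted over or under 1.5-fold. A list's median was placed among 10000 random lists of the same size matched on mean expression, with a counting interval from 200 Poisson draws. Lists covered the Apoa1 gene cluster, tyrosine and phenylalanine catabolism, pericentral, midlobular and periportal genes, S phase and G2/M, p53 and NRF2 targets, fetal and regenerating liver, the Dlk1-Dio3 locus, acute phase, interferon, MHC class I, unfolded protein and integrated stress response, and cholesterol and fatty acid synthesis. Further lists covered fatty acid oxidation, gluconeogenesis and fasting, bile acids, clock, male-biased and female-biased liver, sex chromosomes, coagulation, DNA repair, xenobiotic metabolism, matrix, sinusoidal zones, capillarisation, resident Kupffer and lipid-associated macrophage genes, nuclear RNA and ribosomal proteins, and early response genes.

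No test or p-value between groups was made, since each group had 1 library. Counts of genes past 1.5-fold describe the 2 libraries and carry no significance. Alternatives covered the uncorrected counts, minimum UMIs of 1000 and 200, doublets kept, resolutions 0.4 and 1.6, each library clustered alone, TMM factors (edgeR 4.0.16) and median-of-ratios scaling, means of per-nucleus CPM, thinning to 2000 and 500 UMIs, 3 G2/M genes for a cycling nucleus, other minimum counts per list member, and totals without mitochondrial genes, Malat1 and Neat1. Added after the data were seen were a clustering without the Apoa1 cluster and tyrosine genes, values without cluster 14, the mixed cluster counted as hepatocyte-like, and splits of nuclei by tdTomato, Cas9, eGFP and Abcc4. For the tdTomato split, 5 nuclei without tdTomato per nucleus with it were drawn at matched depth. Of the corrected barcodes, 8335 Control and 7048 Repair Drive ones were also in the uncorrected matrices. Uncorrected values over the same nuclei leave the others out. They cover 5348 of 5392 Control but 3486 of 3986 Repair Drive hepatocyte-like nuclei. A move between the 2 countings can therefore also come from the nuclei left out.

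The gene step was tested on simulated Poisson counts over 32289 genes, drawn from the Control hepatocyte-like profile at the totals of both libraries. Since the interval assumes such counts, this checks the computation and not the spread between nuclei. The 95% interval held the true ratio for 95% of 100 genes changed 1.5-fold, 91% of 100 genes changed 3-fold and 95.7% of 11278 unchanged genes, and 98 of 100 unchanged lists of 20 genes lay inside the central 95% of random lists. Positions are from the GENCODE vM21 annotation of mm10, in which 510 of 512 looked-up genes were found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used.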

Results

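Repair Drive is a liver gene therapy scheme. Adeno-associated viruses (AAV, small viral carriers of DNA) bring the nuclease Cas9 and a donor DNA into hepatocytes, and the donor, with a selectable marker and a therapeutic gene, is placed at the Apoa1 gene. Small interfering RNA (siRNA, short RNA that lowers one gene's messenger) then transiently lowers an essential gene, which depletes hepatocytes that lack the marker. The data are single-nucleus RNA sequencing (snRNA-seq, RNA counted per nucleus) of the liver of 1 Control and 1 Repair Drive C57BL/6J mouse, taken 12 weeks after AAV. The ambient-corrected counts held 49778060 UMIs (unique molecular identifiers, single RNA molecules) in Control and 40696329 in Repair Drive. After filtering, 7548 Control and 6565 Repair Drive nuclei were compared, with medians of 4529.5 and 3623 UMIs per nucleus. With 1 library per group, no replicate check or test between mice was possible. All intervals below are 95% intervals of counting error only, and differences describe these 2 libraries.

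The first question was which cell classes the 2 livers held. Hepatocyte-like nuclei were 71.4% (70.4 to 72.5) of Control and 60.7% (59.5 to 61.9) of Repair Drive nuclei. Endothelial-like nuclei were 10.2% (9.57 to 10.9) and 13.6% (12.8 to 14.5), stellate-like nuclei, the vitamin A-storing cells of the sinusoid, 7.27% (6.70 to 7.88) and 12.0% (11.3 to 12.9), and Kupffer/macrophage-like nuclei 3.50% (3.09 to 3.94) and 6.08% (5.51 to 6.68). Cholangiocyte-like nuclei, of the bile duct lining, were 36 (0.477%) and 73 (1.11%), while T/NK-like (0.702 and 0.518%), B-like (0.278 and 0.259%) and mesothelial-like (0.305 and 0.335%) nuclei were rare in both. A cluster with markers of several classes (cluster 10; 4.90 and 4.34%) and an unnamed cluster (0.888 and 0.944%) stood outside all classes. With a minimum of 1000 UMIs per nucleus the hepatocyte-like share was 78.8% in Control and 82.7% in Repair Drive. The mixed share was then 5.83% in Control and 0.596% in Repair Drive. The turn in direction thus came with a change of the mixed class as well as the loss of shallow nuclei. The endothelial-like share was then 5.29 and 4.96% and the Kupffer/macrophage-like share 2.61 and 2.33%, so their rise was also lost, while stellate-like nuclei stayed higher (5.61 and 7.42%).

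**Figure D1:**
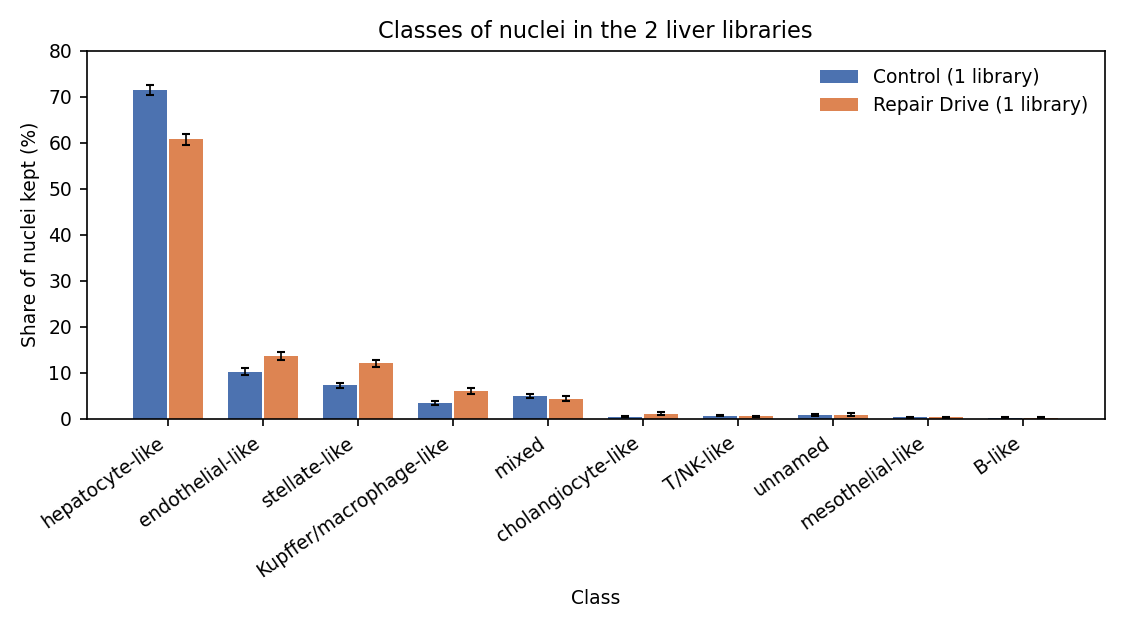
Bars show the share of kept nuclei (%, vertical axis) per class of nuclei (horizontal axis) in the Control and the Repair Drive library (1 each), with exact 95% counting intervals as error bars. Hepatocyte-like nuclei were 71.4 and 60.7%, and stellate-like nuclei 7.27 and 12.0%.

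Hepatocyte-like nuclei of the 2 mice lay in different clusters: clusters 0, 3, 6 and 8 held most of the Control nuclei and clusters 4, 5, 7, 11 and 12 most of the Repair Drive nuclei. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Of 12 hepatocyte-like clusters, 9 held at least 95% of their nuclei from 1 library, and these held 97.1% of the Control and 90.3% of the Repair Drive hepatocyte-like nuclei. Depth was alike, with medians of 5669 UMIs (quartiles 3799 and 8386.75) and 2756 genes in 5392 Control nuclei, and 5853.5 UMIs (3702 and 9605) and 2866 genes in 3986 Repair Drive nuclei. Endothelial-like nuclei, used below as the class that should lack hepatocyte genes, had medians of 959 and 806.5 UMIs. Shares after thinning every nucleus to 1000 UMIs leave out 2 Control and 23 Repair Drive hepatocyte-like nuclei, and 419 and 650 endothelial-like nuclei.

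The second question was which vector genes, and which of the genes Apoa1 and Fah, the hepatocytes expressed. The gene lowered by the siRNA is not given in the sources used here, and Fah was taken as its likely target from the human FAH feature. Both libraries carried vector transcripts, and different ones. Enhanced green fluorescent protein (eGFP) was read in 81.2% (80.1 to 82.2) of Control hepatocyte-like nuclei (543 CPM, counts scaled to the summed counts of the class; 37.3% after thinning) and in no Repair Drive one. Cas9 was read in 32.1% (30.7 to 33.6) of Repair Drive hepatocyte-like nuclei (109.9 CPM; 8.66% after thinning) and in no Control one. The red fluorescent protein tdTomato was read in 229 Repair Drive hepatocyte-like nuclei, 5.75% (5.04 to 6.51; 10.2 CPM), or 46 nuclei and 1.16% (0.851 to 1.55) after thinning, and human FAH in 31 nuclei, 0.778% (0.529 to 1.10; 0.177% after thinning). In endothelial-like nuclei eGFP was read in 1 of 773 Control nuclei (0.129%), Cas9 in 1 of 896 Repair Drive nuclei (0.112%) and tdTomato in none of the 896, which allows up to 0.335%. In Repair Drive stellate-like nuclei tdTomato was read in 3 of 791 (0.379%), Cas9 in 7 (0.885%) and human FAH in 1 (0.126%). In Control stellate-like nuclei eGFP was read in 6 of 549 (1.09%). After thinning, human FAH in hepatocyte-like nuclei is not set apart from stellate-like nuclei, where 0 of 379 allows up to 0.792%. A count of 0 in the hepatocyte-like class allows up to 0.0556% of Control and 0.0753% of Repair Drive nuclei.

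Apoa1 (ENSMUSG00000032083; chromosome 9, 46228580 to 46230466, plus strand, in mm10), which encodes the main protein of high-density lipoprotein and is the integration site, was at 313 CPM (308 to 319) in Control and 159 CPM (155 to 164) in Repair Drive hepatocyte-like nuclei. The share of hepatocyte-like nuclei with an Apoa1 UMI was 62.8 and 31.3%, or 21.2% (20.1 to 22.3) and 9.79% (8.88 to 10.8) after thinning, against 1.41 and 0.813% of thinned endothelial-like nuclei. Stellate-like nuclei held more of it, in 5.48% (3.43 to 8.26) and 7.65% (5.18 to 10.8) of thinned nuclei and at 317 and 192 CPM. In Control 1 stellate-like nucleus held 127 of their 248 UMIs, so the level of 317 CPM leans on it. The Repair Drive share in hepatocyte-like nuclei is not set apart from that class. Of the 4 genes of its cluster, 3 were lower by over 1.5-fold: Apoa4, of chylomicrons, at 14.3 and 2.99 CPM, Apoa1, and Apoa5, an activator of triglyceride clearance, at 399 and 234 CPM. Apoc3, an inhibitor of lipoprotein lipase, was at 52.8 and 66.3 CPM, and its log2 ratio of 0.33 was -0.08 in the uncorrected counts. It was read in 3.65 and 2.02% of thinned hepatocyte-like and in 2.35 and 7.92% of thinned stellate-like nuclei. Cluster 14, with 81 Control and 147 Repair Drive nuclei (medians of 6407 and 2353 UMIs), held much of the RNA of these genes (Apoc3 at 2212 CPM in its Repair Drive nuclei). Its 10 leading genes against the other hepatocyte-like clusters were Mup20, Apoc3 and otherwise mitochondrial genes. Carried-over RNA from outside the nucleus was therefore not told apart there from nuclear levels. Without cluster 14, an alternative added after the values were seen, Apoc3 was at log2 -2.13 and Apoa1 at -1.59 in place of -0.98. The median log2 ratio of the 4 genes was -0.87 (-0.91 to -0.84), at percentile 0.07 of random lists. Without cluster 14 it was -1.86, with Apoa4 at -3.88 in place of -2.26, so the counting interval understates how far it depends on the nuclei summed. Fah, the last enzyme of tyrosine breakdown (ENSMUSG00000030630; chromosome 7, 84585159 to 84606722, minus strand), was at 182 and 163 CPM. The ratio of the 2 levels was 0.895 (0.862 to 0.929), below 1 by more than counting error. A Fah UMI was read in 63.8 and 62.6% of hepatocyte-like nuclei, or 17.1% (16.1 to 18.2) and 16.1% (14.99 to 17.3) after thinning, with overlapping intervals. In endothelial-like nuclei Fah was read in 0.129 and 0.223% (0 of 354 and 0.407% of 246 after thinning). Albumin (Alb) was at 2595 and 2090.3 CPM, and the clotting factor F9 at 54.8 and 61.4 CPM.

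**Figure D2:**
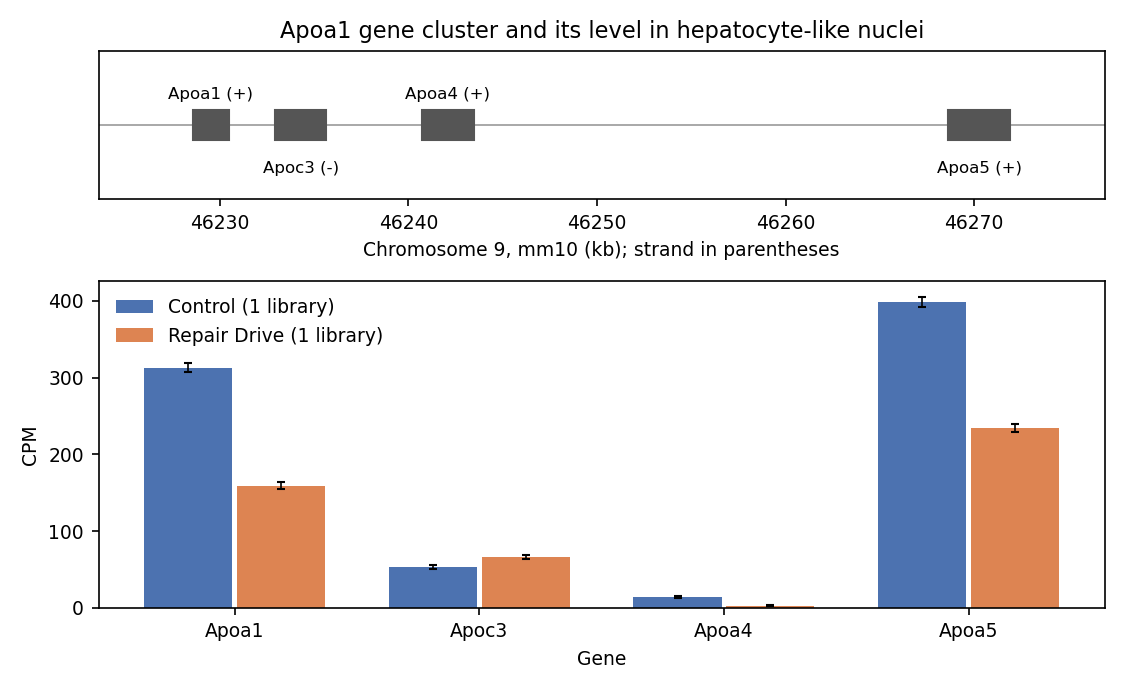
The upper panel draws Apoa1, Apoc3, Apoa4 and Apoa5 to scale on chromosome 9 of mm10 (kb, strand in parentheses), and the bars below give the level of each gene (CPM) in Control and Repair Drive hepatocyte-like nuclei, with exact 95% counting intervals as error bars. Apoa1 was at 313 and 159 CPM and Apoc3 at 52.8 and 66.3 CPM.

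The main question was how hepatocytes differed between the 2 livers across all genes. Besides Cas9, genes nearly silent in Control hepatocyte-like nuclei led the list of higher genes in Repair Drive. Abcc4, an export pump for organic anions (ENSMUSG00000032849; chromosome 14, 118482692 to 118706219, minus strand), was at 1.37 and 576 CPM (422-fold higher). Glypican 3 (Gpc3, a fetal and liver tumour surface protein; ENSMUSG00000055653, X chromosome, 52272426 to 52613950, minus strand) had 1 count in Control and was at 143 CPM in Repair Drive (ratio 5254, counting interval 942 to 207565). Glis3, a zinc-finger transcription factor, was at 1.37 and 169 CPM, Cachd1, related to calcium channel subunits, at 0.164 and 113 CPM, the glutamate transporter Slc1a1 at 0.382 and 32.0 CPM, and Brinp3 at 0.109 and 34.3 CPM. Tinag, a basement membrane protein, had 2 counts in Control and was at 22.2 CPM in Repair Drive (ratio 406, counting interval 112 to 3362). The long RNA 2610307P16Rik was at 1.20 and 118 CPM and the antisense RNA A330015K06Rik at 0.710 and 47.9 CPM. The female-biased cytochromes Cyp2a4 (0 and 77.2 CPM, at least 942-fold) and Cyp2b9 (0.410 and 30.9 CPM) complete the 12, and both have close paralogs: Cyp2a5 was at 98.7 and 377 CPM.

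Of the 11 lowest genes in Repair Drive beside eGFP (at least 5510-fold lower), 3 were on the lipid synthesis lists and 1, Jun, on the early response list. Fasn, fatty acid synthase (ENSMUSG00000025153; chromosome 11, 120805846 to 120824547, minus strand), was at 219 and 32.5 CPM (6.74-fold lower), Thrsp, an inducer of lipogenesis, at 549 and 103 CPM (5.34-fold), and Mvd, of the mevalonate pathway, at 29.4 and 5.49 CPM (5.35-fold). The G protein regulator Rgs16 was at 333 and 18.7 CPM (17.8-fold), the G protein subunit Gna14 at 64.4 and 6.41 CPM (10.04-fold), and the transcription factor Jun at 250.04 and 38.1 CPM (6.57-fold). The antimicrobial peptide Leap2 was at 34.7 and 6.44 CPM, Moxd1 at 47.5 and 6.35 CPM, and the noncoding genes Gm31121, Gm34921 and Gm11773 at 131 and 6.64, 94.3 and 16.7, and 24.6 and 3.09 CPM. The naming rule kept only genes that went the same way by over 1.5-fold in the uncorrected counts. The size of the highest ratios depended on the counting. Of 11 besides Cas9, 5 moved by over 1.5-fold there. Gpc3 went from log2 12.36 to 8.25, outside its counting interval. Cachd1 went from 9.43 to 6.12, Abcc4 from 8.72 to 7.37 and Glis3 from 6.95 to 5.73, and 2610307P16Rik also moved. TMM scaling factors (0.959 and 1.04) would shift all hepatocyte log2 ratios by -0.12 and median-of-ratios scaling by -0.07.

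Lipid synthesis was lower in Repair Drive hepatocyte-like nuclei in step. All 20 measured cholesterol synthesis genes were lower by over 1.5-fold, with a median log2 ratio of -1.47 (-1.52 to -1.37), below all 10000 random lists: Fdft1, squalene synthase, was at 190 and 58.2 CPM and Idi1 at 56.3 and 17.3 CPM. Of 16 fatty acid synthesis genes 12 were lower (median -0.93, -1.02 to -0.84, below all random lists), with Pnpla3, a lipid droplet enzyme, at 4.75 and 0.559 CPM. Fatty acid oxidation genes gave 4 over and 2 under 1.5-fold of 21 (median -0.02, mean 0.15, percentile 16.6), with Acaa1b, a peroxisomal thiolase, at 623 and 475 CPM. Gluconeogenesis and fasting genes had 4 lower of 12 (median -0.33, percentile 0.20; G6pc, which releases glucose, 1811 and 1006 CPM; Igfbp1 log2 -0.78; Sik1 -0.77), and bile acid genes 2 higher and 4 lower of 15 (median -0.09, percentile 7.55; the importer Slco1b2 -0.38; the receptor Nr1h4 0.27; the exporter Abcc2 -0.05). Of 8 tyrosine and phenylalanine catabolism genes, 1 was lower by over 1.5-fold (Hpd, which precedes Fah in the pathway, 828 and 546 CPM; Gstz1 log2 -0.58; Pcbd1 -0.55; list median -0.28, percentile 1.27).

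NRF2 target, p53 target, fetal and cell cycle lists were higher in Repair Drive hepatocyte-like nuclei. Of 20 targets of NRF2, the regulator of antioxidant defence, 15 were higher by over 1.5-fold and none lower (median 1.29, 1.08 to 1.40, above all random lists): Abcc4, the carbonyl reductase Cbr3 (0 and 17.1 CPM, at least 208-fold) and the cystine transporter Slc7a11 (0 and 9.44 CPM, at least 115-fold). Of 18 p53 targets 12 were higher and 2 lower (median 0.86, 0.77 to 0.92, above all random lists), with Eda2r at 2.92 and 29.8 CPM, the cell cycle inhibitor Cdkn1a (p21) at 1.58 and 10.3 CPM, and Phlda3 at 0 and 1.35 CPM (at least 16.5-fold). Of 8 fetal and regenerating liver genes 6 were higher (median 0.91, 0.62 to 1.34, percentile 99.5), among them Gpc3, Sox4 (1 count in Control, 10.8 CPM in Repair Drive; ratio 394, counting interval 70.2 to 15597) and H19 (1 count in Control; ratio 28.9, 4.71 to 1188), whereas alpha-fetoprotein (Afp) was at 6.58 and 6.81 CPM. Sox4 went from log2 8.62 to 7.13 in the uncorrected counts, Slc7a11 from at least 6.85 to 5.63 and Cbr3 from at least 7.70 to 8.41. All 4 measured transcripts of the imprinted Dlk1-Dio3 locus were higher (median 3.60, above all random lists): Meg3 at 21.4 and 256 CPM, Rian at 5.27 and 79.7 CPM, and Mirg at 1.88 and 23.1 CPM. These levels came from few nuclei. Meg3 was read in 0.501 and 6.33% and Rian in 0.334 and 3.89% of thinned hepatocyte-like nuclei, with up to 342 Meg3 UMIs in 1 Repair Drive nucleus. Meg3, Rian and Mirg were among the leading genes of cluster 13, with 20 Control and 216 Repair Drive nuclei.

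Of 16 G2/M genes, 14 were higher by over 1.5-fold (median 1.30, 1.16 to 1.70, percentile 99.8), from low levels: Ccna2, a cyclin, was at 0.109 and 1.02 CPM, Cdk1, the mitotic kinase, at 0.109 and 0.789 CPM, and Top2a, a topoisomerase of dividing cells, at 0.273 and 1.84 CPM. Ccna2 went from log2 3.22 to 1.34 and Cdk1 from 2.85 to 2.03 in the uncorrected counts. Of 16 S phase genes, 8 were higher and 1 lower (median 0.57, percentile 98.2; Mcm6, of the replicative helicase, 3.11 and 9.70 CPM; Mcm2 log2 1.56; Cdc6, 1 count in Control, ratio 26.5, counting interval 4.28 to 1093). For the 11 genes with at least 100 counts the median was 0.23 (percentile 77.1), and the log2 ratio of Cdc6 was 4.73, and 1.82 in the uncorrected counts. Cycling nuclei, with UMIs of at least 2 G2/M genes after thinning, were 3 of 5390 (0.0557%) and 4 of 3963 (0.101%) of hepatocyte-like nuclei, too few to show a difference at this depth. Without thinning they were 1.24% (0.964 to 1.58) and 6.02% (5.30 to 6.80), with intervals that do not overlap, though depth was not matched there. With the mixed cluster counted as hepatocyte-like, an alternative added after the values were seen, cycling nuclei after thinning were 8 of 5760 (0.139%, 0.0600 to 0.273) and 34 of 4247 (0.801%, 0.555 to 1.12). They were 1.69 and 2.85% of endothelial-like, 4.91 and 9.02% of Kupffer/macrophage-like nuclei, and 0 in stellate-like nuclei, which allows up to 0.783 and 0.792%. DNA repair genes gave 4 higher of 19 (median 0.12, percentile 59.4; Prkdc log2 0.31, Atr -0.17, Xrcc5 0.04).

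**Figure D3:**
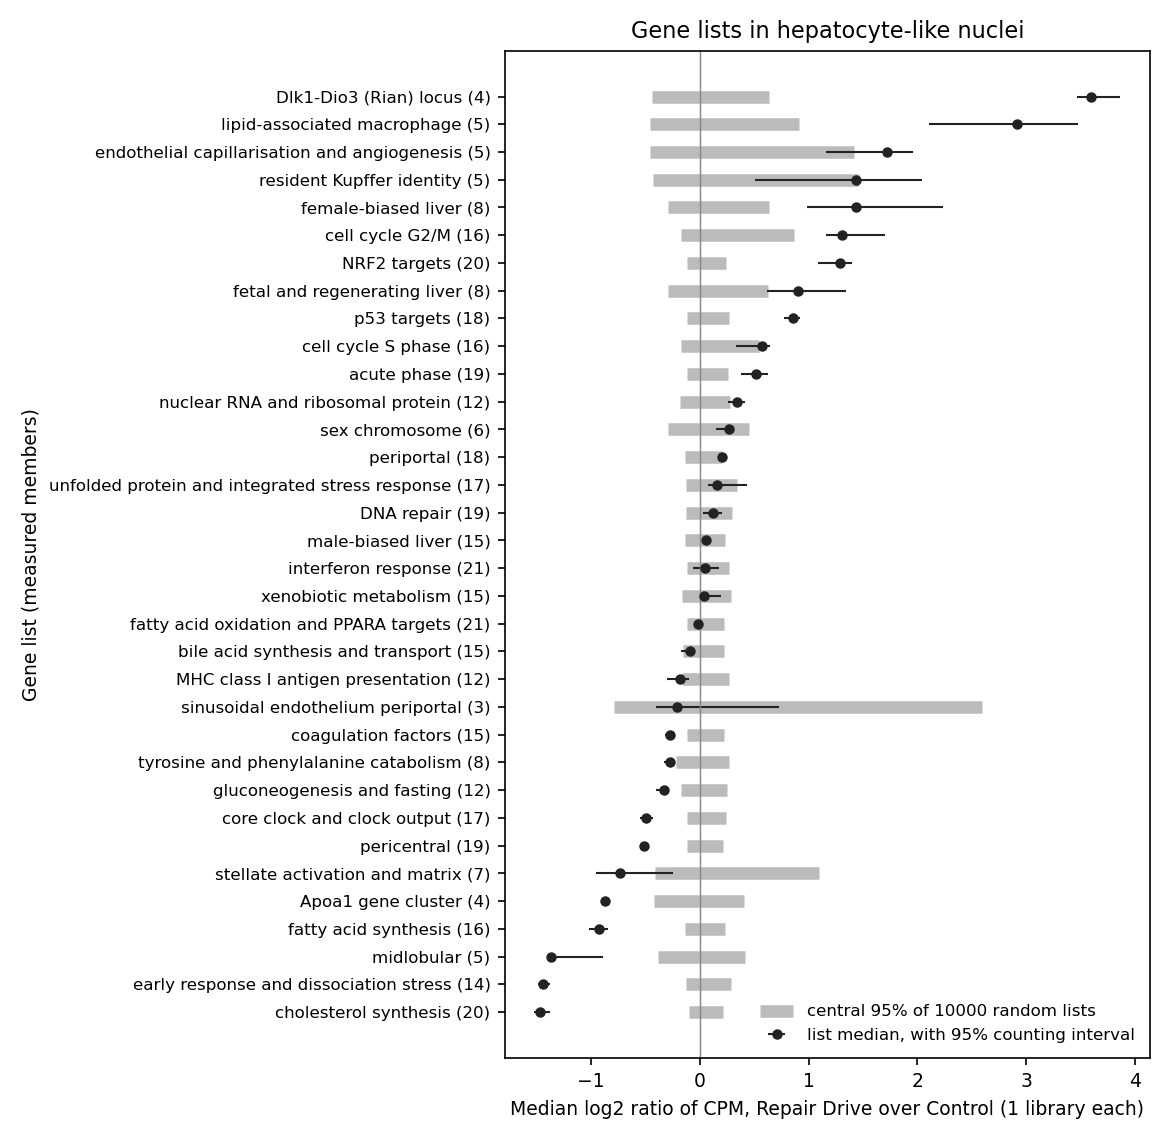
Median log2 ratio of CPM, Repair Drive over Control, of each gene list (vertical axis) in hepatocyte-like nuclei (points, with 95% counting intervals), and the central 95% of the medians of 10000 random lists matched on expression (grey bars). NRF2 targets had a median of 1.29 and cholesterol synthesis genes of -1.47.

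Zonation, the division of labour of hepatocytes from the portal to the central vein, differed in level, and for part of its genes also in the share of nuclei. Of 19 pericentral genes 7 were lower and 2 higher by over 1.5-fold (median -0.52, -0.55 to -0.47, below all random lists), with Cyp2c29, a drug-metabolising cytochrome, at 991 and 373 CPM, the transcription factor Tbx3 at 114 and 53.5 CPM and Rgn at 118 and 64.6 CPM. Of 18 periportal genes 7 were higher and 2 lower (median 0.21, 0.19 to 0.23, percentile 97.53, but 87.1 in the uncorrected counts): Hsd17b6 at 104 and 210.3 CPM, Aldh1b1 at 2.87 and 8.45 CPM and Sdsl at 5.16 and 9.77 CPM. Glul, glutamine synthetase, an enzyme of hepatocytes next to the central vein, was read in 10.9 and 9.66% of thinned hepatocyte-like nuclei (0.565 and 0.813% of endothelial-like nuclei), and the pericentral cytochrome Cyp2e1 in 35.7 and 32.1% (0 and 1.63%). The periportal genes Cyp2f2 and Hal were read in 23.8 and 22.3% and in 28.4 and 27.6% (in at most 0.407% of thinned endothelial-like nuclei). Without thinning, Cyp2e1 was read in 52.3 and 65.9%, Cyp2f2 in 52.0 and 63.0% and Hal in 53.4 and 62.2%, against 22.4 and 22.8% for Glul. At least 2 Cyp2e1 UMIs were in 20.8 and 12.7% of thinned nuclei. Unthinned, Cyp2e1, Cyp2f2 and Hal were thus read in more Repair Drive nuclei, which the thinned shares do not show. Thinned shares of 5 further genes, picked after the values were seen, differed more. The pericentral Cyp2c29 was read in 35.3 and 20.6% and Cyp2a5 in 7.42 and 19.8%. The periportal Hsd17b6 was read in 9.05 and 16.3%, Ass1 in 37.8 and 49.2% and Etnppl in 19.1 and 27.2% (in at most 2.03% of thinned endothelial-like nuclei). The pericentral share of zonation UMIs per thinned nucleus had a median of 14.3% in Control (quartiles 0 and 44.4) and 13.04% in Repair Drive (3.70 and 33.3), or 14.3 and 13.5% unthinned. Nuclei above 75% were 10.4 and 7.81%, and nuclei below 25% were 58.8 and 66.1%. Midlobular genes had 3 lower and 1 higher of 5 (median -1.37, percentile 0.015): Hamp, the iron hormone hepcidin, was at 1052 and 406 CPM, Hamp2 at 2.43 and 0.822 CPM, and Cyp8b1, of bile acid synthesis, at 104 and 28.0 CPM. The same 5 genes were at -0.73 (-1.21 to -0.50) in the uncorrected counts, where Hamp2 went from log2 -1.56 to -0.73.

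Acute phase genes were 9 higher and 2 lower of 19 (median 0.51, 0.38 to 0.62, above all random lists): serum amyloids Saa1 (0.464 and 18.7 CPM) and Saa2 (0.492 and 9.77 CPM), which share sequence, and Lcn2 (2 counts in Control, ratio 20.5, counting interval 5.25 to 176). Without cluster 14, led mostly by mitochondrial genes, the list median was 0.14 (percentile 70.3). Saa1 fell from log2 5.33 to 1.53, Saa2 from 4.31 to 0.37 and Lcn2 from 4.36 to 1.61. Interferon response genes were 1 higher and 5 lower of 21 (median 0.04, mean -0.31, percentile 35.7; Stat2 log2 0.14, Iigp1 0.24). MHC class I presentation genes had 2 lower of 12 (median -0.18, percentile 1.86; H2-D1 32.3 and 12.9 CPM, H2-K1 log2 -0.61, Psmb9 -0.57). In the uncorrected counts the list was at -0.06 (percentile 8.76), and H2-D1 went from -1.32 to -0.52. Unfolded protein and integrated stress response genes were 7 higher and 1 lower of 17 (median 0.16, percentile 67.3; the chaperone Hspa5 64.1 and 98.2 CPM, Herpud1 log2 -0.48, Atf4 0.14). Coagulation genes had 3 lower and 1 higher of 15 (median -0.27, percentile 0.09; fibrinogen chains Fgg 221 and 56.0 CPM and Fgb 334 and 185 CPM; F11 log2 -0.80). Fgg went from log2 -1.98 to -1.01 in the uncorrected counts and Fgb from -0.86 to -0.57, under 1.5-fold. Xenobiotic metabolism genes split 5 and 3 of 15 (median 0.04, percentile 35.9; Cyp2c29; Aldh1a1 log2 0.18; Por 0.04).

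Of 8 measured female-biased liver genes 6 were higher and 2 lower (median 1.44, 0.98 to 2.24, percentile 99.9, with Cyp2a4 and Cyp2b9 among those higher). Male-biased genes were 5 higher and 5 lower of 15 (median 0.05, percentile 45.5; Cyp7b1, of oxysterol metabolism, 555 and 1398 CPM; Cyp2d9 644 and 355 CPM; Nudt7 log2 0.05). The Y-linked Uty, Ddx3y and Eif2s3y were at log2 0.23, 0.32 and 0.34 (6 sex chromosome genes, median 0.27, 1 over and 1 under 1.5-fold, percentile 86.0). Core clock and clock output genes had 5 lower and 1 higher of 17 (median -0.49, -0.55 to -0.44, below all random lists): the output gene Dbp was at 81.0 and 37.1 CPM, Bhlhe41 at log2 -1.23, and the core activator Arntl at 13.8 and 33.7 CPM. Early response genes, which also follow tissue handling, were 12 lower and 1 higher of 14 (median -1.44, -1.49 to -1.38, below all random lists; Jun, Fosb 4.62 and 0.559 CPM, Egr1 90.8 and 22.1 CPM). Nuclear RNA and ribosomal protein genes, a list that mixes nuclear RNAs with messengers of ribosomal proteins, had 3 higher and 1 lower of 12 (median 0.34, percentile 99.2, but 96.6 without cluster 14; Neat1 2542 and 4577 CPM, Rps3 log2 1.48, Rplp0 1.03), with Malat1 at 49352 and 30272 CPM. Over all kept nuclei Malat1 was 4.80 and 3.08% of UMIs and mitochondrial genes were 0.0505 and 0.0731%. A difference in carried-over RNA from outside the nucleus was not tested.

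Lists made for other liver cells were also read in hepatocyte-like nuclei, most members at low levels. Of 7 matrix genes 4 were lower and 1 higher (median -0.73, percentile 0.315; Col4a1 7.89 and 1.87 CPM, Col4a2 log2 -1.88, Fn1, which hepatocytes also make, 1227 and 713 CPM). The 7 genes had a median of -0.77 in the uncorrected counts, and the 13 then measured one of 0.08 (percentile 15.3). Col4a1 went from log2 -2.07 to -0.78 and Col4a2 from -1.88 to -1.18. Of 5 endothelial capillarisation genes 3 were higher (median 1.72, percentile 98.7, but -0.46 with doublets kept; Mecom log2 2.97, Pecam1 1.85, Stab2 1.72), and of 3 periportal sinusoid genes Ntn4 was higher (median -0.21, mean 0.52, percentile 17.3; Jag1 -0.21). Resident Kupffer genes were 3 higher and 1 lower of 5 (median 1.44, percentile 97.4, but -0.81 with doublets kept; Clec4f log2 2.15, Id3 -1.19, Nr1h3 0.11). Of 5 lipid-associated macrophage genes 4 were higher (median 2.91, percentile 99.98), with lipoprotein lipase (Lpl) at 0 and 12.0 CPM (at least 146.9-fold), Spp1, osteopontin, at 0.191 and 1.61 CPM and Cd9 at 0.519 and 3.91 CPM. Their log2 ratios of at least 7.20, 3.08 and 2.91 were 3.43, 0.66 and 1.41 in the uncorrected counts. The list was at 1.12 there, and at 0.77 (percentile 96.6) with no minimum of counts.

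Repair Drive hepatocyte-like nuclei were not uniform. This split, and the genes of this paragraph, were chosen after the values were seen. An Abcc4 UMI was read in 21.2% of thinned Repair Drive hepatocyte-like nuclei and in 0.111% of Control ones, but also in 18.6 and 4.88% of thinned Control and Repair Drive endothelial-like nuclei. The 842 thinned nuclei with an Abcc4 UMI more often held UMIs of Gclc, of glutathione synthesis (75.4 against 27.1% of the 3121 without), Gstm1, a glutathione transferase with close paralogs (21.9 and 5.96%), Gpc3 (22.3 and 2.66%), Mdm2, the p53 inhibitor (25.9 and 13.6%), Eda2r (4.28 and 1.47%) and Cdkn1a (2.14 and 0.352%). They less often held UMIs of Apoa1 (2.49%, 1.55 to 3.79, against 11.8%, 10.6 to 12.9), Alb (52.1 and 74.4%), tdTomato (0.238 and 1.41%) and Cas9 (6.18 and 9.32%), but not of human FAH (2 nuclei, 0.238%, and 5 nuclei, 0.160%). The growth factor receptor Egfr and the growth factor Igf1 set the other nuclei apart: an Egfr UMI was in 63.3% of nuclei with Abcc4 and 93.2% of those without, against 56.3% of Control nuclei without Abcc4, and an Igf1 UMI in 28.0, 66.9 and 28.4%. In thinned endothelial-like nuclei of Control and Repair Drive, Egfr was read in 0.282 and 6.91%, Igf1 in 0.565 and 0.407%, Gclc in 0.565 and 2.03% and Alb in 2.82 and 2.85%. Eda2r was read there in 3.95% of Control nuclei and 0 of 246 Repair Drive nuclei, which allows up to 1.22%. Cdkn1a was read there in 0.282 and 0.813%, so its share is not set apart from background. Over all hepatocyte-like nuclei Egfr was at 953 and 4893 CPM and Igf1 at 362 and 1106 CPM. Before thinning, the nuclei with Abcc4 had a median of 7063.5 UMIs and those without 5604.

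**Figure D4:**
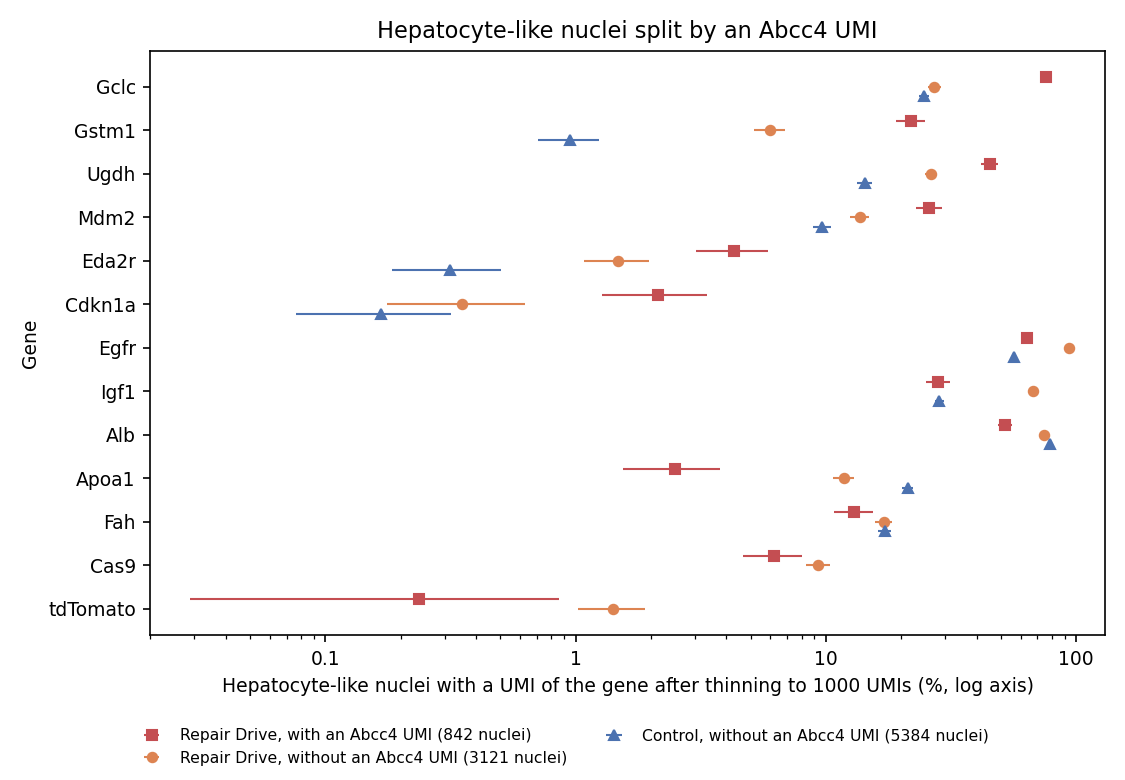
Share of thinned hepatocyte-like nuclei with a UMI of each gene (%, log axis) in Repair Drive nuclei with (842) and without (3121) an Abcc4 UMI and in Control nuclei without one (5384), with exact 95% counting intervals; shares of 0 are not drawn. Gclc was read in 75.4, 27.1 and 24.7%, and Apoa1 in 2.49, 11.8 and 21.2%.

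The last question was how other liver cells differed. For these shallower classes the choice of corrected or uncorrected counts decided much of the picture. Of eligible genes past 1.5-fold, 254 of 844 endothelial-like, 205 of 562 Kupffer/macrophage-like and 303 of 808 stellate-like ones passed it the same way uncorrected. The 3 highest and 3 lowest eligible genes of each class are given with both countings. In endothelial-like nuclei these were Gnpat (1 count in Control, ratio 67.7, counting interval 11.7 to 2712; uncorrected log2 0.92), Zfp64 (3 counts in Control, ratio 32.5, 10.8 to 160.2; uncorrected 1.01) and Arap2 (6.03 and 188 CPM, uncorrected 0.96). The lowest were Aass, of lysine breakdown (806 and 12.4 CPM, uncorrected 0.03), the water channel Aqp1 (187 and 0 CPM, uncorrected -0.53) and the peptide transporter Slc15a2 (128 and 0 CPM, uncorrected 80.3 and 0 CPM). In Kupffer/macrophage-like nuclei they were the iron store Fth1 (0 and 132 CPM, uncorrected 1.01), the hepatocyte gene Mup20 (0 and 506 CPM, uncorrected 0.48) and Apoe (1 count in Control, ratio 129.7, counting interval 22.9 to 5156, uncorrected 0.34). The lowest there were Inpp4a (173 and 10.4 CPM, uncorrected -0.73), Sec22a (152 and 5.19 CPM, -1.15) and Lars (176 and 5.19 CPM, -1.19). In stellate-like nuclei they were Adgrl4 (1 count in Control, ratio 50.8, 8.76 to 2042; uncorrected 1.36), Saa1 (2 counts in Control, ratio 31.6, 8.44 to 266; uncorrected 5.94) and Tmem68 (2 counts in Control, ratio 22.7, 5.98 to 193; uncorrected 0.68), and, lower, Rbm10 (84.3 and 3.42 CPM, uncorrected -0.43), Slc38a9 (129 and 2.28 CPM, -0.49) and Shld1 (71.5 and 1.14 CPM, -0.99). The genes below went the same way by over 1.5-fold in both countings, a condition added after the values were seen, which does not fix the size of the ratio. In stellate-like nuclei Fhl2, a cytoskeletal cofactor, was at 7.66 and 59.2 CPM, the acute phase protein Orm1 at 23.0 and 153 CPM (ratio 6.64, uncorrected 3.68), Ptprt, a receptor phosphatase, at 827 and 271 CPM and Tafa2 at 159.7 and 33.0 CPM (4.84-fold lower, uncorrected 3.12). In endothelial-like nuclei the neurexin Nrxn3 was at 4.82 and 74.2 CPM (log2 3.94, uncorrected 1.32), the transcription factor Runx1 at 9.65 and 55.6 CPM (log2 2.53, uncorrected 1.25) and the DNA glycosylase Mbd4 at 72.4 and 19.8 CPM. In Kupffer/macrophage-like nuclei Tspan7 was at 36.5 and 145 CPM, Creb5 at 54.7 and 176 CPM, the interferon-inducible Gbp2b at 277 and 88.2 CPM, and H2-Eb1, of MHC class II, at 191 and 80.4 CPM.

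Among the lists, acute phase genes were higher in both countings in stellate-like (14 genes, median 1.30, uncorrected 0.67 for the same genes) and Kupffer/macrophage-like nuclei (5 genes, 3.19, uncorrected 1.14). Albumin, a hepatocyte transcript, was still read after the correction in 7.31% of Control and 44.6% of Repair Drive stellate-like nuclei after thinning, and in 4.91 and 31.1% of Kupffer/macrophage-like nuclei, so the values of both classes lie beside more hepatocyte RNA in Repair Drive. Resident Kupffer genes were lower in Kupffer/macrophage-like nuclei (9 genes, -0.35, uncorrected -0.62), and MHC class I genes in endothelial-like nuclei (10 genes, -0.63, uncorrected -0.41). Nuclear RNA and ribosomal protein genes were higher in the same 2 classes, at 2.05 in Kupffer/macrophage-like nuclei (6 genes, uncorrected 0.55) and 1.55 in endothelial-like nuclei (3 genes, uncorrected 0.52). Lists that differed in hepatocyte-like nuclei also moved elsewhere. NRF2 targets were higher in endothelial-like nuclei (5 genes, 2.28, uncorrected 1.24), where Gclc was at 3.62 and 33.4 CPM but Abcc4 at 230 and 117 CPM. Egfr, also higher in Repair Drive hepatocyte-like nuclei, was at 3.62 and 156 CPM there. Alb was at 65.1 and 134 CPM, though in 2.82 and 2.85% of thinned nuclei. Carried-over hepatocyte RNA was not told apart from a change in endothelial-like nuclei. In stellate-like nuclei cholesterol synthesis genes were at -0.81 (3 genes, percentile 14.3) and fatty acid synthesis genes at -0.61 (9 genes, percentile 3.27), inside the random lists, and for the same genes at -0.54 and -0.74 in the uncorrected counts. The 17 and 16 genes measured there were below all random lists (-0.67 and -0.58). Fatty acid synthesis genes were also lower in Kupffer/macrophage-like nuclei (3 genes, -2.62, uncorrected -0.97). Carried-over hepatocyte RNA, in which both lipid synthesis lists were lower, was not told apart from a change in stellate-like or Kupffer/macrophage-like nuclei. The pericentral sinusoid genes, not measurable in hepatocyte-like nuclei, had a median of -0.06 in endothelial-like nuclei (5 genes, uncorrected -0.24, percentile 10.4). The capillarisation genes were at -0.14 there (9 genes, uncorrected -0.33, percentile 2.32), and the matrix genes at -0.21 in stellate-like nuclei (12 genes, uncorrected -0.29 for 13 genes, percentile 0.50), so both lists lay outside the random lists in the uncorrected counts.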

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

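The checks of the ambient correction on cholesterol synthesis and on Gpc3 were chosen only after the results were seen. So were those of nuclei without an expressed donor and of depth in cycling nuclei. The differences between cell classes below were not tested.

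In 4 cases a gene list lay outside the random lists in hepatocyte-like nuclei and, with the opposite sign, in another class. In the uncorrected counts, given here for the same genes, each interval included 0. Pericentral genes had a median log2 ratio of 3.09 in endothelial-like nuclei (3 genes, uncorrected 0.09, -0.23 to 0.42) against -0.52 in hepatocyte-like nuclei. Coagulation genes were at 1.2 in Kupffer/macrophage-like nuclei (3 genes, uncorrected 0.18, -0.005 to 0.76) and at 0.66 in stellate-like nuclei (11 genes, uncorrected 0.10, -0.03 to 0.26), against -0.27 in hepatocyte-like nuclei. Core clock and clock output genes were at 1.88 in stellate-like nuclei (7 genes, uncorrected 0.09, -0.09 to 0.32) against -0.49 in hepatocyte-like nuclei.

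Vector genes were also read in barcodes left out of the comparisons. Of the 1166 Repair Drive barcodes left out (median 1612 UMIs), 103 held a tdTomato UMI, 8.83% (7.27 to 10.6), and 168 a Cas9 UMI, 14.4% (12.4 to 16.6). None of the 884 Control ones (median 5421.5 UMIs) held either, which allows up to 0.339%. This contrast tells little, since Control hepatocyte-like nuclei held neither gene, and 708 of the 884 (80.1%) held an eGFP UMI. In the deeper Repair Drive hepatocyte-like nuclei, tdTomato was read in 5.75% and Cas9 in 32.1%.

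In the mixed cluster, outside all classes, 10.6% of thinned Repair Drive nuclei (30 of 284, 7.24 to 14.7) and 1.35% of Control nuclei (5 of 370) held UMIs of at least 2 G2/M genes. The shares were taken at 1 depth and their difference exceeds counting error. This cannot decide on deeper sequencing of the Repair Drive nuclei, since the result was flagged on these same thinned shares. The 30 nuclei held hepatocyte markers (Alb at 1438 CPM) and, together, endothelial, Kupffer/macrophage and stellate markers at 702 CPM (599 to 818), against 1054 in the other nuclei of the cluster and 51.2 in hepatocyte-like nuclei. Dividing hepatocytes and doublets of a hepatocyte with a dividing cell of another class cannot be told apart here, because that level is lower than in the rest of the cluster but far above that of hepatocyte-like nuclei. The difference may also belong to the mouse and not the treatment, which 1 library per group leaves open.

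Cholesterol synthesis genes were lower in Repair Drive hepatocyte-like nuclei, with a median log2 ratio of -1.47 in the corrected counts. The ambient correction is argued against by the same median, -1.47 (-1.54 to -1.39), in the uncorrected counts, and a cause in only part of the nuclei by the highest median among the 7 hepatocyte-like clusters with at least 100 Repair Drive nuclei, -1.04 (-1.16 to -0.99, cluster 5). Time of day at collection cannot be told apart from the treatment. Clock activators against outputs were at 1.25 (1.05 to 1.42) in hepatocyte-like nuclei and at -1.62 (-2.47 to -1.19) in the other classes together, but the bound set for this test was void, since the other classes were at -0.11 (-0.66 to 0.28) before ambient correction. A difference in feeding, handling or treatment could each go with such a change and stays untested.

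Gpc3 and Abcc4 were read in a part of the Repair Drive hepatocyte-like nuclei, mostly in clusters 4 and 11. In the uncorrected counts 25.4% (24.0 to 26.9) of the 3486 Repair Drive and 0.337% of the 5348 Control hepatocyte-like nuclei found there held a Gpc3 UMI. This cannot decide on the ambient correction, since both genes were named only if higher by over 1.5-fold in those counts. A tdTomato UMI was in 0.503% (0.218 to 0.990) of thinned nuclei of clusters 4 and 11 and in 1.601% (1.14 to 2.19) of the other Repair Drive hepatocyte-like nuclei, but a human FAH UMI in 3 (0.189%, 0.0390 to 0.551) and 4 nuclei (0.168%, 0.0459 to 0.431). Whether these are hepatocytes without an expressed donor cannot be told: tdTomato had already been seen to differ by Abcc4, human FAH was too rare, and which of them marks the donor is not given in the sources used here. With 1 mouse the state may also belong to that liver.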

How the results depend on the processing

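Leaving out cluster 14 and counting the mixed cluster as hepatocyte-like were chosen only after the results were seen. Of the log2 ratios of the genes picked by the rule for named genes in hepatocyte-like nuclei, 739 values under alternatives stayed within the main interval, 224 moved out of it, and 5, of genes past 1.5-fold, reversed. Of the list medians 223 stayed, 77 moved and 3, of lists outside the random lists, reversed. In the other classes these were 248, 27 and 1 for genes and 327, 63 and 3 for lists. Among the other values, the sign changed in 10 of 963 for genes and 12 of 300 for lists in hepatocyte-like nuclei, and in 0 of 275 and 25 of 390 in the other classes, each where the main value was within 1.5-fold or inside the random lists. Of 24 lists outside the random lists in hepatocyte-like nuclei, 16 stayed outside on the same side under each of 6 alternatives. For this check, added after the values were seen, random lists were drawn again. The other 8 did not. Periportal (percentile 87.1) and MHC class I genes (-0.06) went inside in the uncorrected counts, acute phase (0.14) and nuclear RNA and ribosomal protein genes without cluster 14, S phase genes with at least 100 counts (0.23) and lipid-associated macrophage genes with no minimum of counts (0.77). Matrix genes went inside in the uncorrected counts and with doublets kept, and capillarisation genes inside in the uncorrected counts and to the other side with doublets kept. Part of these 8 also went inside under further alternatives. Of 67 named genes past 1.5-fold, leaving out the highest and lowest, which had to pass it in the uncorrected counts to be named, 62 passed it the same way there and the ratios of 23 moved by over 1.5-fold. A list with under 3 measured members under an alternative gave no value there. Values that moved are given below for the leading results, and the cause was not tested unless stated.

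The hepatocyte-like share in Control and Repair Drive was 67.1 and 50.95% in the uncorrected counts, 78.8 and 82.7% with at least 1000 UMIs, 76.3 and 64.1% with at least 200 UMIs, 77.5 and 66.4% with doublets kept, and 74.4 and 65.3% with each library clustered alone, and in Repair Drive 64.6% at resolution 1.6. Only the minimum of 1000 UMIs turned its direction. By construction it drops the shallow nuclei of the other classes, but the mixed share also went from 4.90 to 5.83% in Control and from 4.34 to 0.596% in Repair Drive. The turn therefore cannot be put down to the shallow nuclei alone. With at least 200 UMIs or with doublets kept, no cluster was set aside as mixed.

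TMM factors, which shift all log2 ratios alike, gave Fah -0.28, Apoa1 -1.1, pericentral -0.64, periportal 0.09, p53 targets 0.74, cholesterol -1.59 and fatty acid synthesis -1.05. Median-of-ratios scaling gave Fah -0.23, Apoa1 -1.05, pericentral -0.59, periportal 0.14 and cholesterol -1.54. Means of per-nucleus CPM gave Apoa1 -0.7, pericentral -0.46, p53 targets 0.71, NRF2 targets 0.98 and fatty acid synthesis -0.84. A minimum of 1000 UMIs gave Apoa1 -1.06 and pericentral -0.56, and doublets kept gave periportal 0.25. Uncorrected counts gave Apoa1 -1.04, periportal 0.16, NRF2 targets 1.42 and fatty acid synthesis -1.08. Without cluster 14 Apoa1 was at -1.59.

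Thinning to 2000 UMIs raises shares by construction: Fah was read in 30.9 and 28.2% and Apoa1 in 35.2 and 13.9% of Control and Repair Drive hepatocyte-like nuclei, and cycling nuclei were 0.192 and 0.478%. At 500 UMIs Fah was read in 9.16 and 8.08%, Apoa1 in 11.9 and 6.297%, and cycling Control nuclei were 0. With doublets kept Fah was read in 15.9987% of Control nuclei, Apoa1 in 20.02 and 8.25%, and cycling nuclei were 0.2395 and 0.958%. No cluster was set aside as mixed there, so these moves cannot be put down to the doublets alone. In the uncorrected counts Apoa1 was read in 38.1 and 19.5%, the median zonation index of Control was 18.2%, and median depth was 6130.5 and 7081 UMIs. With 3 G2/M genes required, cycling nuclei were 0 in both. With 2 required and the mixed cluster included, they were 0.139% (0.0600 to 0.273) in Control and 0.801% (0.555 to 1.12) in Repair Drive, whose intervals do not overlap.

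With doublets kept, Ntn4 (-0.51), Mecom (-0.09), Pecam1 (-0.49), Stab2 (-0.46), Clec4f (-0.59) and the capillarisation list (-0.46) reversed in hepatocyte-like nuclei. No cluster was set aside as mixed in that setting, and hepatocyte-like nuclei were 6266 in Control and 4619 in Repair Drive, against 5392 and 3986. These reversals therefore cannot be put down to the doublets alone. In the uncorrected counts Aass (0.03) and the pericentral list (-0.23) reversed in endothelial-like nuclei, the matrix list (0.08) in hepatocyte-like nuclei and gluconeogenesis (0.16) in Kupffer/macrophage-like nuclei. More members are measured there. Over the members measured after correction the pericentral, matrix and gluconeogenesis lists were at 0.09 (3 genes), -0.77 (7 genes) and 0.11 (5 genes). The matrix and pericentral changes of sign thus came with the added members. The fall of the pericentral median from 3.09 to 0.09 came with the counting or with nuclei missing from the uncorrected matrices. The matrix list was also at 0.27 with no minimum of counts, and Kupffer/macrophage coagulation at -0.32 with at least 1000 UMIs. Depth limits the other classes most, with medians near 1000 UMIs.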

Other observations

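Except for the cluster medians of cholesterol synthesis, the comparisons in this part were chosen only after the results were seen, and no test between the parts was made.

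Repair Drive hepatocyte-like nuclei with a tdTomato UMI (229 nuclei, median 8214 UMIs) were set beside 1145 nuclei without one at matched depth (median 8194). Apoa1 was at 379 CPM with and 118 CPM without tdTomato, and at 148 and 63.3 CPM when cluster 14 was left out, so the direction held without that cluster. The imprinted RNA Meg3 was at 736 and 233 CPM, Alb at 3266 and 1840.2 CPM and the urinary protein gene Mup17 at 167 and 15.4 CPM. Gpc3 was at 73.6 and 191 CPM, the p53 target Eda2r at 16.6 and 35.2 CPM and the imprinted Peg3 at 58.6 and 158 CPM, while Cas9 was at 138 and 105 CPM. As lists, the Apoa1 gene cluster had a median log2 ratio of 1.54 (1.22 without cluster 14), the Dlk1-Dio3 locus 1.66, acute phase genes 0.96, p53 targets -0.42 and NRF2 targets -0.25, nuclei with over those without tdTomato. Only Apoa1 and its gene cluster are given without cluster 14, so how far the other values lean on it is open. Both tdTomato and Alb were higher in left-out barcodes with many mitochondrial UMIs, given below. Carried-over RNA was thus not told apart in this contrast.

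The Repair Drive clusters differed in the same lists when each was set against all Control hepatocyte-like nuclei. NRF2 targets had medians of 2.00 in cluster 4 and 1.81 in cluster 11, against -0.29 in cluster 5 and -0.15 in cluster 7, and lay between in clusters 12 (0.29), 13 (0.71) and 14 (1.12). For p53 targets these were 1.40, 1.29, -0.25, -0.02, 0.40, 0.43 and 0.11, and for cholesterol synthesis genes, lower in all 7, -1.46, -1.58, -1.04, -1.32, -1.85, -1.81 and -1.09. Apoa1 was at 11.2 CPM in cluster 4 and 40.7 CPM in cluster 11, against 138 and 109.5 CPM in clusters 5 and 7.

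Of the Repair Drive barcodes left out, 413 had over 5% mitochondrial UMIs (median 1778 UMIs), and in these tdTomato was at 126 CPM, against 10.2 CPM in hepatocyte-like nuclei. Apoa1 was at 6832 and 159 CPM, Alb at 48132 and 2090.3 CPM, Cas9 at 91.9 and 109.9 CPM and the nuclear RNA Malat1 at 7368 and 30272 CPM. In the 220 Control barcodes of this kind eGFP was at 970.1 CPM and Apoa1 at 14293 CPM.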
